A study of Mus musculus with 2 samples.

How the data were processed

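Myeloid cells of mouse blood were measured by single-cell RNA sequencing 24 h after a transient occlusion of the proximal middle cerebral artery, with 1 library from young mice (2 to 4 months) and 1 from aged mice (18 to 24 months), all C57BL/6. Per the labels, cells were sorted as CD11b+ Ly6G− and CD11b+ Ly6G+ and the libraries were made with the 10x 3′ v2 kit. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse genome mm10. The values are raw UMI counts per gene and cell as deposited by the authors, who gave each cell a population label. Whether mice were pooled, in what proportion the sorted fractions were mixed, and how the authors filtered cells are not given in the sources used here. Immunoglobulin and T cell receptor genes and Xist were not analysed here.

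The table held 11691 genes and 5793 cells, 1849 from the young and 3944 from the aged library. Totals were 6440664 and 13752454 UMIs, medians 2022 and 2219 UMIs and 646 and 621 genes per cell, and lowest depths 1260 and 1451 UMIs. The highest mitochondrial share was 7.23% and 7.91%. In neutrophils the median was 1636.5 and 1914 UMIs, and in monocytes 6604 and 6366. Of all genes, 854 had no UMI in any young cell and stood in 1 closing block of the table, and 129 had none in the aged library. No gene with a UMI was found in fewer than 3 cells of a library, which points to a filter on genes in each library that the sources used here do not state. Genes at 0 in 1 library were given no ratio.

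A filter of at least 200 genes, at least 500 UMIs and at most 10% mitochondrial UMIs removed 0 cells. Doublet scores came from scrublet as built into scanpy. Its automatic threshold called only 4 young and 2 aged cells, so the cells with the highest scores were removed at the planned rate of 8 per 1000 cells for each 1000 cells, 27 (1.46%) in the young and 124 (3.14%) in the aged library. The main cell types were the authors' labels, which were used in place of a clustering planned earlier, once the file was found to hold them. Own clusters were made from counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 nearest neighbours and the Leiden method, and named from fixed marker lists. Both libraries were clustered together without integration, at resolution 1.

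Counts were summed over the cells of each population in each library and divided by the population's total to give CPM. Sums have exact Poisson intervals, ratios of aged over young exact conditional binomial intervals, and shares of cells Clopper-Pearson intervals, all at 95%. With 1 library per group there is no replicate, so no test was made and no p-value is given. The intervals hold counting error alone and leave out the spread between mice and between libraries. Single genes needed 50 UMIs summed over both libraries, and genes in lists 20 UMIs.

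The genes to be named, the 28 gene lists for neutrophils and 21 for monocytes, the markers, the filters and the first set of alternatives were fixed before the data were examined. Named were the 12 genes with the highest and the 12 with the lowest ratio in neutrophils, and 10 each in monocytes, ranked by the interval bound nearest to 1. Ribosomal protein, mitochondrial, globin, sex-linked, immunoglobulin and T cell receptor genes, pseudogenes and unnamed gene models were left out of that ranking. They numbered 307 in neutrophils, of which 1 was at least 2-fold higher and 61 lower, and 431 in monocytes, of which 4 were higher and 51 lower. The code that recognises pseudogenes was written after values had been seen. Of each list, up to 4 measured genes with the highest counts or the largest ratios could be named as examples. Which of these to print was chosen after their values were seen, and so were the monocyte genes for shares of cells with a UMI.

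Each list is summarised by its members at least 1.5-fold higher or lower and by the median log2 ratio of its measured members. The percentile gives the place of that median among 10000 random lists of the same size drawn from 20 bins of expression. It describes these libraries and is not a test. For the effect of other settings, the median of matched lists was subtracted from that of the list, a choice made after the median of all neutrophil genes was seen at −0.24.

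For values per cell, each cell was thinned at random without replacement to 500 UMIs. No cell was too shallow for this. Shares of cells with a UMI were set beside those of 83 young and 99 aged NK and B cells as a guide to free RNA, which reads too high for transcripts that NK or B cells make themselves. Neutrophils were also clustered alone at resolution 0.5. Gene positions came from GENCODE M21, where 608 of 610 gene names were matched.

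Alternatives were no filter on cells, at least 500 genes and 1000 UMIs per cell, no doublet removal, own clusters at resolutions 0.5 and 2, and each library clustered alone. Others were ribosomal and mitochondrial genes left out of the total, TMM scaling, the mean of each cell's CPM, and cells thinned to 500 UMIs. Further ones were minimums of 10 UMIs for list genes and 20 for single genes, a minimum of 200, thinning to 1000 UMIs or none for values per cell, and neutrophil clustering at resolutions 0.3 and 1. Own clusters at resolution 1 as cell types, and the same lowest depth of 1451 UMIs in both libraries, were added after seeing the data, as were NK cells without those that own clusters put under T cells.

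The method was tested on simulated data with the real means and totals, after the real tables had been made. Counts were drawn as Poisson sums from a mean shared by both libraries, with no spread between cells, mice or libraries, so the simulation covers counting error alone. With no difference, the ratio interval held 1 for 95.8% of 4742 neutrophil genes and 95.6% of 7791 monocyte genes. In neutrophils, with 50 genes at each size, the interval held the true fold for 90% at 1.5-fold, 100% at 2-fold, 98% at 4-fold and 96% at 0.5-fold. It lay on the right side of 1 for 64%, 96%, 100% and 74%. In monocytes, again with 50 genes each, it held the fold for 98%, 96%, 98% and 96% and lay on the right side of 1 for 82%, 98%, 100% and 84%. Of 100 lists with no difference, 2% in neutrophils and 7% in monocytes lay outside the middle 95% of random lists. All of 20 lists shifted by 1.5-fold lay above it in both populations.

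Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9 and edgeR 4.0.16, the last for TMM factors, which were 1.11 and 0.898 in neutrophils and 1.00 and 0.997 in monocytes.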

Results

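Blood myeloid cells of C57BL/6 mice were profiled by droplet single-cell RNA sequencing 24 h after a transient occlusion of the proximal middle cerebral artery, an experimental model of ischemic stroke. The young group held mice of 2 to 4 months and the aged group mice of 18 to 24 months, each with 1 library. The young library held 1849 cells with 6440664 UMIs, and the aged library 3944 cells with 13752454 UMIs. Median depth was 2022 UMIs per cell in the young and 2219 in the aged library. With 1 library per age, no difference reported here has a replicate check, and each statement compares these libraries, not ages. Intervals are 95% and cover counting error only.

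The first question was how the sorted blood cells divided among cell types in each library. Neutrophils were the main population in both, at 62.3% of 1822 young cells (exact binomial interval 60.1% to 64.6%) and 68.5% of 3820 aged cells (67.0% to 70.0%). Monocytes made up 29.5% (27.4% to 31.7%) of the young and 24.7% (23.3% to 26.1%) of the aged library. NK cells were at 3.79% (2.96% to 4.77%) in the young and 1.52% (1.15% to 1.96%) in the aged library. Conventional dendritic cells were at 2.85% and 2.75%, and follicular B cells at 0.768% (0.421% to 1.29%) and 1.07% (0.771% to 1.45%). Cells that the authors labelled Eryth-Neutro made up 0.714% (0.380% to 1.22%) and 0.393% (0.220% to 0.647%). Cells labelled Mast cell were 42 of the aged library, 1.10% (0.794% to 1.48%). None of the 1822 young cells had that label, with an interval of 0 to 0.202%.

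Sorting on CD11b and Ly6G, and a lowest depth of 1260 UMIs in the young against 1451 in the aged library, can set these shares. When the cells were clustered anew at resolution 2, clusters named by monocyte markers held 454 of 1822 young and 313 of 3820 aged cells. That clustering gave 365 cells led by Spp1 and Dmkn (34 young, 331 aged) a progenitor name and 203 cells led by C1q genes (39 young, 164 aged) a dendritic name, though the authors labelled most of both as monocytes. Cells it kept as classical monocytes were split by library, in a cluster of 297 young and 32 aged cells and another of 50 and 197. Leading genes of the first included Fn1, Wdr89 and the ribosomal pseudogene copies Rps26-ps1, Rps18-ps3, Rpl13-ps3 and Rpl10-ps3. Such copies were lower in aged monocytes as a whole, with a median log2 ratio of −1.44. Whether the split follows kinds of monocyte or the reads given to such copies was not tested.

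**Figure D1:**
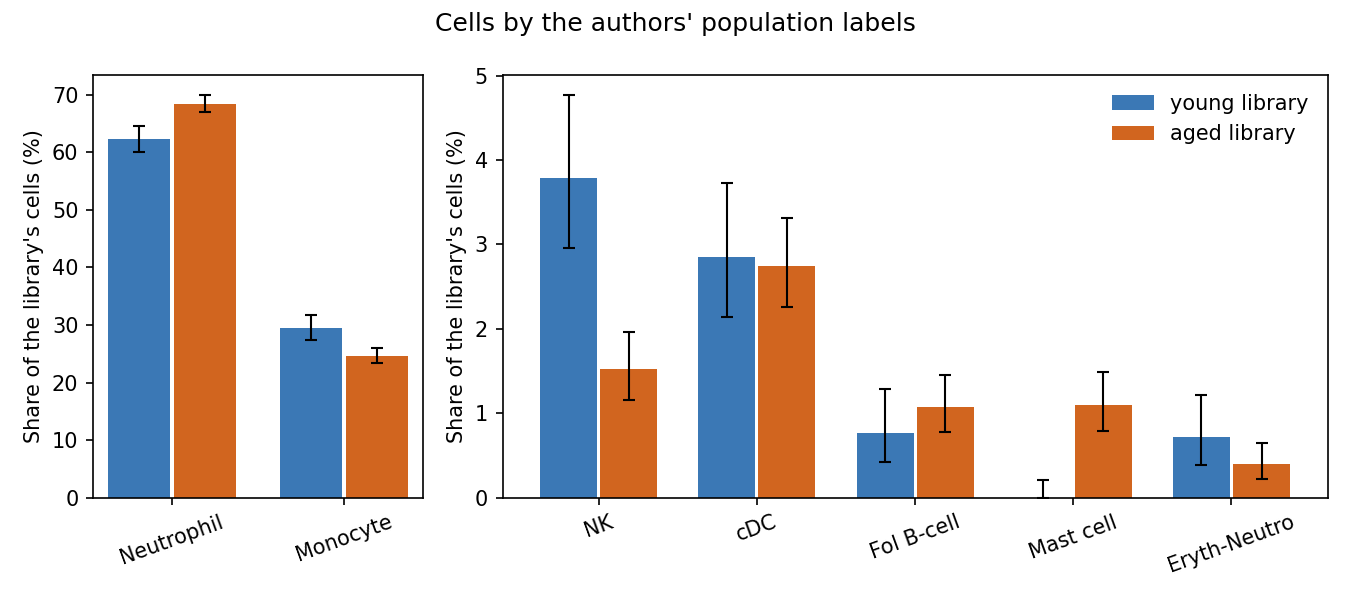
Share of each library's cells (%, vertical axes) by the authors' population label, young in blue and aged in orange, with a separate scale for the rarer populations. Bars are shares of 1822 young and 3820 aged cells and error bars are exact 95% binomial intervals; neutrophils stood at 62.3% and 68.5%, and Mast cell at 0 and 1.10%.

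The second question was which transcripts differed between circulating neutrophils of the aged and young libraries. Camp and Ltf, transcripts of specific granule proteins, were higher in the aged library. Of 16 measured genes in the specific granule list, 5 were at least 1.5-fold higher there and 1 lower. Camp, which encodes the antimicrobial cathelicidin, was at 15.7 CPM (UMI counts scaled to the total of the population) in the young and 93.6 CPM in the aged neutrophils, a ratio of 5.95 (4.16 to 8.80). Ltf, which encodes the iron-binding granule protein lactoferrin, had 2 UMIs in the young and 65 in the aged library, a ratio of 12.2 (3.23 to 103). Ribosomal protein genes and immediate early transcription factor genes were lower in the aged library, among them Junb at a ratio of 0.475 (0.453 to 0.498). Values came from 1136 young and 2616 aged neutrophils with 2034954 and 5438562 UMIs.

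Among the other genes that ranked highest in aged neutrophils, Serpinb1a, an inhibitor of neutrophil serine proteases, had a ratio of 3.89 (3.11 to 4.94). Ifitm6, of the interferon-induced transmembrane family, was abundant at 1256 and 3759 CPM, a ratio of 2.99 (2.87 to 3.12). Il1r2, the decoy receptor that binds interleukin-1, was at 572 and 1210 CPM, a ratio of 2.12 (1.99 to 2.26). Cxcl3, a chemokine that attracts neutrophils, had a ratio of 4.45 (2.75 to 7.65). Thbs1, which encodes thrombospondin 1, had a ratio of 3.21 (2.38 to 4.43), and Cd38, an enzyme that consumes NAD, of 3.97 (2.33 to 7.25). Hilpda, a lipid droplet protein induced in hypoxia, had 2 young and 61 aged UMIs, a ratio of 11.4 (3.03 to 96.4). Ratios were 5.31 (2.17 to 16.9) for Adamtsl4 and 3.87 (2.14 to 7.69) for Ecm1, both extracellular matrix genes. Hist2h2aa1, a histone H2A gene, had a ratio of 4.41 (3.30 to 6.01), which is uncertain because near-identical histone copies share reads. On GRCm38/mm10, Camp lies on chromosome 9 from 109847379 to 109849617, Ltf on chromosome 9 from 111019271 to 111042767, Ifitm6 on chromosome 7 from 141015699 to 141017924, and Il1r2 on chromosome 1 from 40074079 to 40125231.

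Among the genes that ranked lowest, Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, had a ratio of 0.175 (0.101 to 0.296). Gm2a, the activator of GM2 ganglioside breakdown, was at 279 and 83.8 CPM, a ratio of 0.301 (0.265 to 0.341). Lst1, a leukocyte-specific transcript, was at 1197 and 442 CPM, a ratio of 0.369 (0.349 to 0.391), and Retn, which encodes resistin, had a ratio of 0.303 (0.243 to 0.377). Prr5l, which encodes a binding partner of the mTORC2 kinase complex, had a ratio of 0.183 (0.123 to 0.267). Ratios were 0.232 (0.151 to 0.351) for Nap1l1, a histone chaperone gene, and 0.215 (0.123 to 0.368) for Eef2k, the kinase of elongation factor 2. Vwa1 had a ratio of 0.209 (0.113 to 0.377) and Grcc10 of 0.335 (0.276 to 0.406). Psme2b, a near-identical copy of a proteasome activator gene, had a ratio of 0.249 (0.152 to 0.405), which is uncertain for shared reads. Gzma, the cytotoxic granule protease of NK and T cells, had a ratio of 0.227 (0.144 to 0.354), in libraries where NK cells were 3.79% and 1.52% of cells. Wdr89 had a ratio of 0.236 (0.208 to 0.267) in neutrophils and lay close to it in the other populations, at 0.296 in monocytes, 0.331 in dendritic cells and 0.308 in NK cells.

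Of 4740 neutrophil genes with at least 50 UMIs, 47 were at least 2-fold higher in the aged library and 253 at least 2-fold lower. Simulated libraries with no difference, which held Poisson counting error alone, gave 21 and 6 of 4742 genes. The median log2 ratio of all genes was −0.24, and S100a8, S100a9 and Retnlg took 33.0% of young and 41.7% of aged neutrophil UMIs. With TMM scaling that median was 0.07 and the split was 131 higher and 95 lower, and with ratios centred on their median it was 105 and 116. The split was 171 and 536 in cells thinned to 500 UMIs, 126 and 561 with genes from 20 UMIs, and 14 and 66 with genes from 200 UMIs. Gene lists are therefore described by their place among 10000 random lists of genes with matched expression, which a common scaling factor does not move. Counts of list members at least 1.5-fold apart are given with total scaling and do move. With TMM scaling they became 14 higher and 0 lower of 22 immature, 8 and 0 of 16 specific granule, 5 and 0 of 14 gelatinase granule, 1 and 7 of 22 mature, 6 and 5 of 21 maturation surface, 1 and 8 of 21 AP-1, 1 and 6 of 32 interferon, 3 and 4 of 26 NF-kappaB and 0 and 12 of 68 ribosomal protein genes. They also became 1 and 0 of 40 oxidative phosphorylation, 5 and 3 of 22 chemotaxis and 5 and 3 of 22 pattern recognition genes. Further counts were 3 and 1 of 7 S100, 4 and 0 of 13 extracellular trap, 5 and 2 of 25 glycolysis and 2 and 1 of 16 phagocytosis genes.

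**Figure D2:**
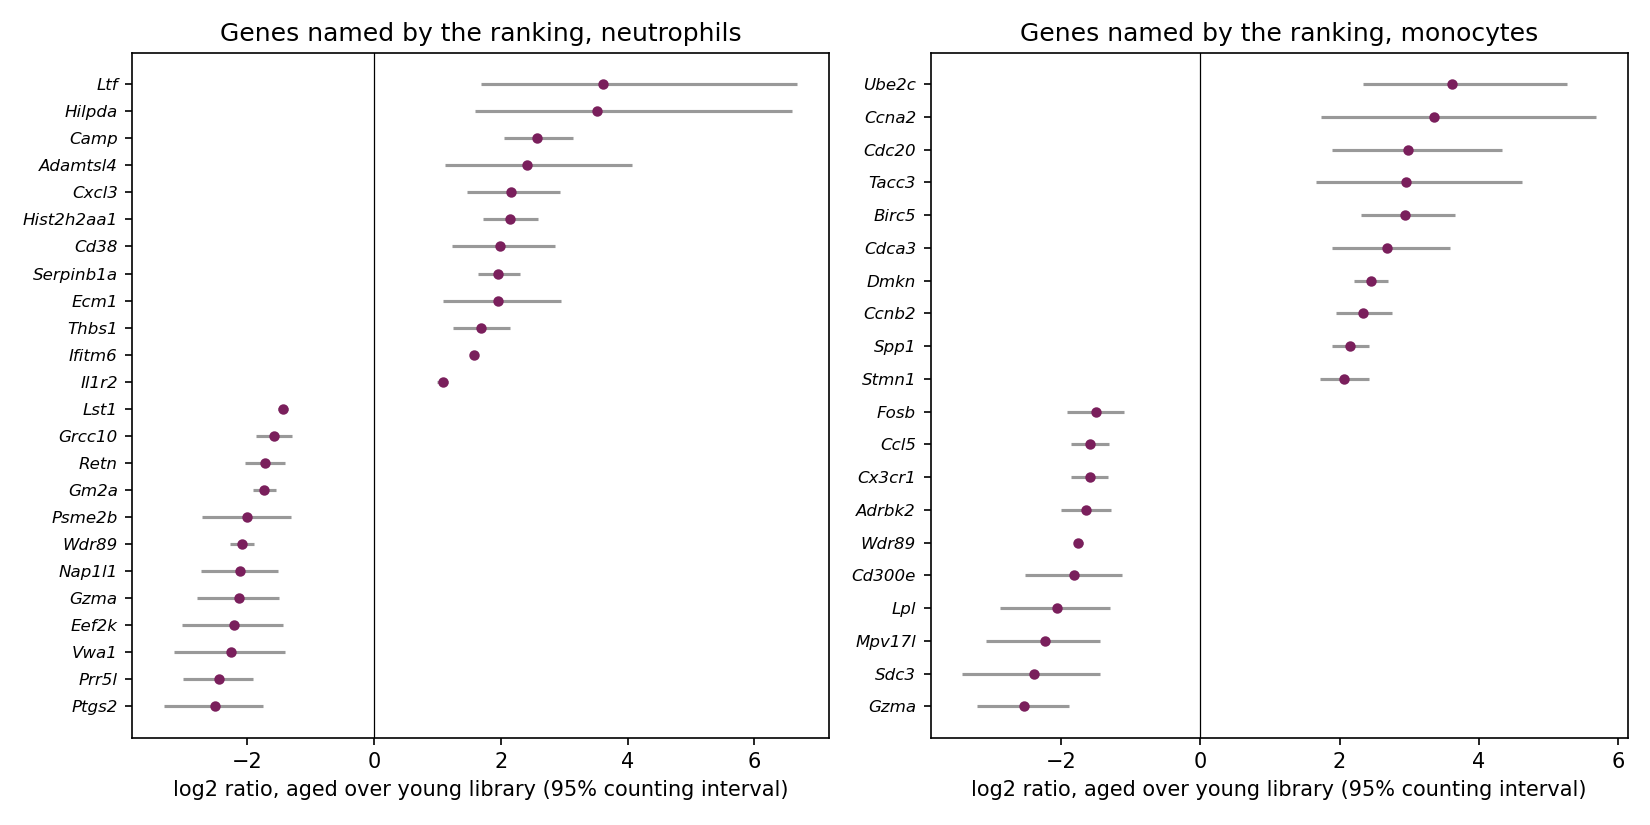
Log2 ratio of aged over young CPM (horizontal axes) for the genes named by the ranking rule, in neutrophils (left) and monocytes (right). Points are ratios and lines exact 95% counting intervals; Camp in neutrophils lies at 2.57, and Ube2c in monocytes at 3.61.

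Granule and maturation lists were compared next. Of 22 measured genes of immature neutrophils, 7 were at least 1.5-fold higher in the aged library, 2 lower and 13 between, with a median log2 ratio of 0.42 at percentile 100. Ly6g, the surface antigen used in the sort, had a ratio of 1.89 (1.76 to 2.04), Retnlg, a resistin-like gene, 1.39 (1.38 to 1.40), and Cd177, a neutrophil adhesion glycoprotein, 1.36 (1.20 to 1.55). Members of that list also went the other way: Hmgn2, a nucleosome-binding protein gene, was at 0.571 (0.515 to 0.632) and Lyz2, which encodes lysozyme, at 0.660 (0.639 to 0.682). Wfdc21 was at 0.864 (0.849 to 0.878), and its log2 ratio of −0.21 became 0.10 with TMM scaling. Specific granule genes, of which 10 are also in the immature list, had a median of 0.29 at percentile 100, with 5 of 16 higher and 1 lower. Lcn2, the iron-sequestering lipocalin, was at 1.27 (1.25 to 1.30). Ltb4r1, 1 of the 5 higher, was at 2.04 (1.80 to 2.32). It encodes the leukotriene B4 receptor and also stands in the chemotaxis list, so not all 5 are genes of granule proteins. Azurophilic granule genes had a median of 0.23 at percentile 98.6 over only 5 measured genes, 1 higher and 1 lower, with the granule membrane gene Cd63 at 1.28 (1.13 to 1.45). Gelatinase and secretory granule genes had a median of 0.11 at percentile 99.9, with 2 of 14 higher and 1 lower. Mmp8, neutrophil collagenase, was at 1.34 (1.28 to 1.40), and Slpi, a protease inhibitor, at 0.652 (0.637 to 0.669). In cells thinned to 500 UMIs the excess of this list over matched lists went from 0.35 to 0.23.

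Genes of mature neutrophils had a median of −0.45 at percentile 1.94, with 10 of 22 lower and none higher by 1.5-fold. Of these 10, 5 also stand in the AP-1 or the ribosomal list, including Junb, Jund, Dusp1 and Rps27. Il1b, the inflammatory cytokine, was at 0.516 (0.495 to 0.538), and Malat1, a nuclear noncoding RNA, at 0.740 (0.731 to 0.748), while Ifitm2 was at 1.33 (1.30 to 1.36). Surface markers of maturation and ageing had a median of −0.01 at percentile 99.3, with 2 of 21 higher and 6 lower. Cxcr4, the receptor for bone marrow retention, was at 0.50 (0.405 to 0.619), Cd101 at 0.366 (0.240 to 0.560) and the integrin gene Itga4 at 0.393 (0.304 to 0.508), while Cd14 was at 1.82 (1.66 to 2.00). The transcription factor genes of granulopoiesis had a median of −0.08 at percentile 93.1, with 0 of 15 higher and 3 lower. Irf8 was at 0.445 (0.239 to 0.837), and Cebpb at 0.945 (0.911 to 0.982), a log2 ratio of −0.08 that became 0.23 with TMM scaling. The excess of this list over matched lists went from 0.17 to 0.31 with the same lowest depth of 1451 UMIs in both libraries.

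Per neutrophil, with each cell thinned to 500 UMIs and no cell left out, the immature list took a median of 6.6% of UMIs in the young and 9.2% in the aged library. The quartiles were 4.6% and 9% in the young, and 6.75% and 11.4% in the aged library, and the unthinned medians were 6.52% and 9.25%. Retnlg, at 45546 and 63308 CPM, was the most abundant gene of that list. By these pooled values it held most of the list's share and most of the gap between the libraries, so the share per cell mainly follows this single gene. The mature list took 7.4% and 6% of UMIs per cell, and 7.37% and 6.05% unthinned. At 500 UMIs the median number of genes per neutrophil was 226 in the young and 196 in the aged library. Clustering of neutrophils alone gave 4 clusters at resolution 0.5. A cluster led by Ccl4, Gm12840 and Il1b held 79.7% of the young and 43.2% of the aged neutrophils, and one led by Camp, Ngp and Serpinb1a 18.3% and 53.3%. At resolution 0.3 a single cluster held 99.7% and 98.9%, and at resolution 1 a cluster led by Rps27rt, Gm9843 and Wdr89 held 75.9% and 2.87% and one led by Camp, Ngp and Serpinb1a 5.46% and 31.9%, so the division rests on the resolution. Their leading genes include genes that differed between the libraries, so the sizes are no separate finding, and the maturation values may come from another mix of cells and do not show a change within 1 kind of cell.

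A Ly6g UMI was found in 15.9% (13.9% to 18.2%) of young and 27.8% (26.1% to 29.6%) of aged neutrophils at 500 UMIs, and in 38.7% and 64.1% without thinning. In NK and B cells the shares were 0 of 83 and 2 of 99 thinned, and 4.82% and 14.1% unthinned. Median depth was 1632 and 1899 UMIs in neutrophils and 2079 and 2654 in NK and B cells. Cxcr2, the chemokine receptor for release from marrow and migration, was seen in 32.9% and 32.5% of neutrophils thinned and 74.7% and 75.8% unthinned, against 2.41% and 3.03%, and 7.23% and 12.1%, in NK and B cells. Its CPM ratio was 0.921 (0.870 to 0.976), and the log2 ratio of −0.12 became 0.19 with TMM scaling. Cd177 was seen in 7.48% and 8.45% thinned and 20.1% and 30.1% unthinned, against 1.20% and 0, and 2.41% and 6.06%. Cxcr4 was seen in 4.14% and 1.80% thinned and 12.6% and 7.42% unthinned, against 1.20% and 1.01%, and 4.82% and 10.1% in NK and B cells, which express it too. For Isg15, a ubiquitin-like interferon-induced gene, shares were 5.28% and 3.29% thinned and 12.4% and 11.2% unthinned, against 1.20% and 0, and 4.82% and 10.1%. Camp UMIs were found in 0.792% and 2.29% of neutrophils thinned, 2.38% and 5.93% unthinned, and in none of 83 and 99 NK and B cells. Ltf UMIs were found in 0 and 4 cells thinned, in 2 of 1136 and 22 of 2616 unthinned, and in no NK or B cell. Cd101 UMIs were found in 15 and 5 cells thinned and in 3.87% and 1.80% unthinned, against 1.20% and 2.02% unthinned in NK and B cells.

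Inflammatory gene groups differed in how far they lay from other genes of the aged neutrophils. AP-1 and immediate early genes had a median log2 ratio of −0.77 at percentile 0, with 13 of 21 lower and none higher. Fosb was at 0.206 (0.105 to 0.393), Jund at 0.505 (0.474 to 0.538) and Dusp1, a MAP kinase phosphatase gene, at 0.585 (0.563 to 0.607), while Klf2 was at 1.26 (1.20 to 1.32). Among genes from 200 UMIs the distance of the AP-1 list from matched lists went from −0.53 to −0.27. Interferon-stimulated genes had a median of −0.46 at percentile 3.61, with 13 of 32 lower and none higher, among them Rsad2, which encodes the antiviral viperin, at 0.367 (0.243 to 0.553) and Slfn8 at 0.221 (0.102 to 0.459). Isg15 was at 0.732 (0.621 to 0.864) and Slfn4 at 1.22 (1.01 to 1.48). NF-kappaB targets and cytokines had a median of −0.37 at percentile 8.34, with 2 of 26 higher and 11 lower, Ccrl2 at 0.348 (0.221 to 0.548) among the latter. MHC class I genes had a median of −0.38 at percentile 15.9, with 4 of 13 lower, Psmb8 of the immunoproteasome at 0.578 (0.506 to 0.660) and H2-D1 at 1.10 (1.06 to 1.14). S100 alarmin genes had a median of 0.18 at percentile 99.5 with 1 of 7 lower and none higher by 1.5-fold. S100a8 and S100a9, the subunits of calprotectin, were at 1.21 (1.21 to 1.22) and 1.30 (1.29 to 1.30), S100a6 was at 1.34 (1.31 to 1.36) and S100a4 at 0.518 (0.409 to 0.657). Genes of extracellular trap formation had a median of 0.09 at percentile 99.8, with 1 of 13 higher, Mmp9 at 1.12 (1.06 to 1.17) and the pore-forming Gsdmd at 0.745 (0.595 to 0.938), and the excess over matched lists went from 0.33 to 0.57 in thinned cells. Pattern recognition receptor and inflammasome genes had a median of 0.00 at percentile 99.5, with 2 of 22 higher, including the lipopolysaccharide co-receptor Cd14, and 4 lower.

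Effector groups lay within or near the range of matched lists. Chemotaxis, adhesion and transmigration genes had a median of −0.11 at percentile 93.4, with 2 of 22 higher and 6 lower, and the formyl peptide receptor genes Fpr1 and Fpr2 at 1.69 (1.5 to 1.90) and 1.46 (1.35 to 1.58). Phagocytosis and Fc or complement receptor genes had a median of −0.07 at percentile 94.3, with 2 of 16 lower. C5ar1, the complement C5a receptor, was at 1.33 (1.24 to 1.43) and the kinase gene Syk at 0.631 (0.546 to 0.729). Fcer1g was at 0.921 (0.898 to 0.944), a log2 ratio of −0.12 that became 0.19 with TMM scaling. NADPH oxidase and oxidative burst genes had a median of −0.13 at percentile 85.0, with 1 of 14 lower, the oxidase subunit gene Ncf1 at 1.17 (1.04 to 1.32) and mitochondrial superoxide dismutase Sod2 at 0.583 (0.372 to 0.925). Apoptosis and survival genes had a median of −0.16 at percentile 78.9, with 2 of 21 higher and 2 lower. Pmaip1, a pro-apoptotic BH3-only gene, was at 0.210 (0.101 to 0.419) and Cflar, a caspase-8 inhibitor, at 1.51 (1.17 to 1.96). Mcl1, a neutrophil survival gene, was at 0.832 (0.780 to 0.888), a log2 ratio of −0.27 that became 0.05 with TMM scaling. Senescence genes had a median of 0.09 at percentile 98, with 1 of 7 lower, and an excess over matched lists that went from 0.32 to 0.15 with genes from 10 UMIs. Cell cycle genes had a median of −0.13 at percentile 78.5 over 6 measured genes, 1 of them lower, and heat shock genes −0.19 at percentile 69.3, with 1 of 14 higher and 4 lower.

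Ribosomal protein genes were lower in aged neutrophils, with a median log2 ratio of −0.67 at percentile 0 and 48 of 68 lower by 1.5-fold, or 12 of 68 with TMM scaling. Rps28 was at 0.362 (0.324 to 0.404), Rps27 at 0.488 (0.473 to 0.503) and Rps9 at 0.773 (0.755 to 0.792). Ribosomal pseudogene copies, which share reads with these genes, had a median of −1.79 in neutrophils and of −1.44 in monocytes. Mitochondrially encoded genes had a median of −0.44 at percentile 7.88, with 4 of 12 lower. Among them were mt-Nd2 at 0.510 (0.393 to 0.662), mt-Co3 at 0.792 (0.750 to 0.836) and mt-Co1 at 0.856 (0.823 to 0.890), whose log2 ratio of −0.22 became 0.09 with TMM scaling. Nuclear genes of oxidative phosphorylation had a median of −0.31 at percentile 14.9, with 7 of 40 lower and none higher, and Atp5k at 0.546 (0.480 to 0.622). Glycolysis and hypoxia genes had a median of −0.05 at percentile 98.8, with 3 of 25 higher and 3 lower, Hk1 at 2.20 (1.29 to 4.00) and Hk2 at 0.365 (0.229 to 0.582), both hexokinase genes of the first glycolytic step. With the same lowest depth of 1451 UMIs in both libraries, a setting chosen after seeing the data, the excess of the glycolysis list over matched lists went from 0.20 to 0.10.

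Transcripts of other cell types were lower in aged neutrophils alongside these groups. Of 12 monocyte transcripts 9 were lower and none higher, with a median of −0.92 at percentile 0, and Fn1 and Csf1r, the fibronectin and M-CSF receptor genes, were at 0.469 (0.343 to 0.644) and 0.495 (0.383 to 0.642). Ly6c2 was at 1.15 (1.06 to 1.26), and 3 of the list's 13 genes also stand in another neutrophil list. All 5 measured lymphocyte transcripts were lower, with a median of −1.66 at percentile 0.005, including the cytotoxic granule gene Nkg7 at 0.317 (0.171 to 0.581) and the chemokine gene Ccl5 at 0.397 (0.315 to 0.499). Erythroid and platelet transcripts had a median of −1.84 at percentile 0, with 4 of 6 lower and 2 higher. The hemoglobin gene Hbb-bs was at 0.268 (0.246 to 0.292). The platelet chemokine genes Ppbp and Pf4 were at 3.18 (1.36 to 9.07) and 1.80 (1.12 to 3.03), and both lay below 1 with each library clustered alone. The aged library alone gave a cluster led by Ppbp and Pf4, with 75 cells labelled neutrophils, and the young library alone gave none, so that this setting compares unlike cells. At resolution 1 such a cluster held 4 young and 55 aged cells labelled neutrophils.

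Other neutrophil genes named here had a ratio that differed by more than 1.5 times from the value above under a further setting, given here as log2. With at least 500 genes and 1000 UMIs per cell it became 4.37 for Hilpda and 2.28 for Ppbp. Resolution 0.5 of own clusters gave 0.72 for Ppbp. With each library clustered alone it became −2.78 for Hbb-bs. Resolution 1 of own clusters gave 0.72 for Ppbp. With the same lowest depth in both libraries it became 4.16 for Hilpda. In cells thinned to 500 UMIs it became 3.04 for Adamtsl4, −2.79 for Cd101, 0.74 for Ecm1, −1.20 for Fosb, −1.62 for Pmaip1, −2.90 for Psme2b, −3.11 for Ptgs2, −0.18 for S100a4, −2.79 for Slfn8 and −0.011 for Sod2.

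**Figure D3:**
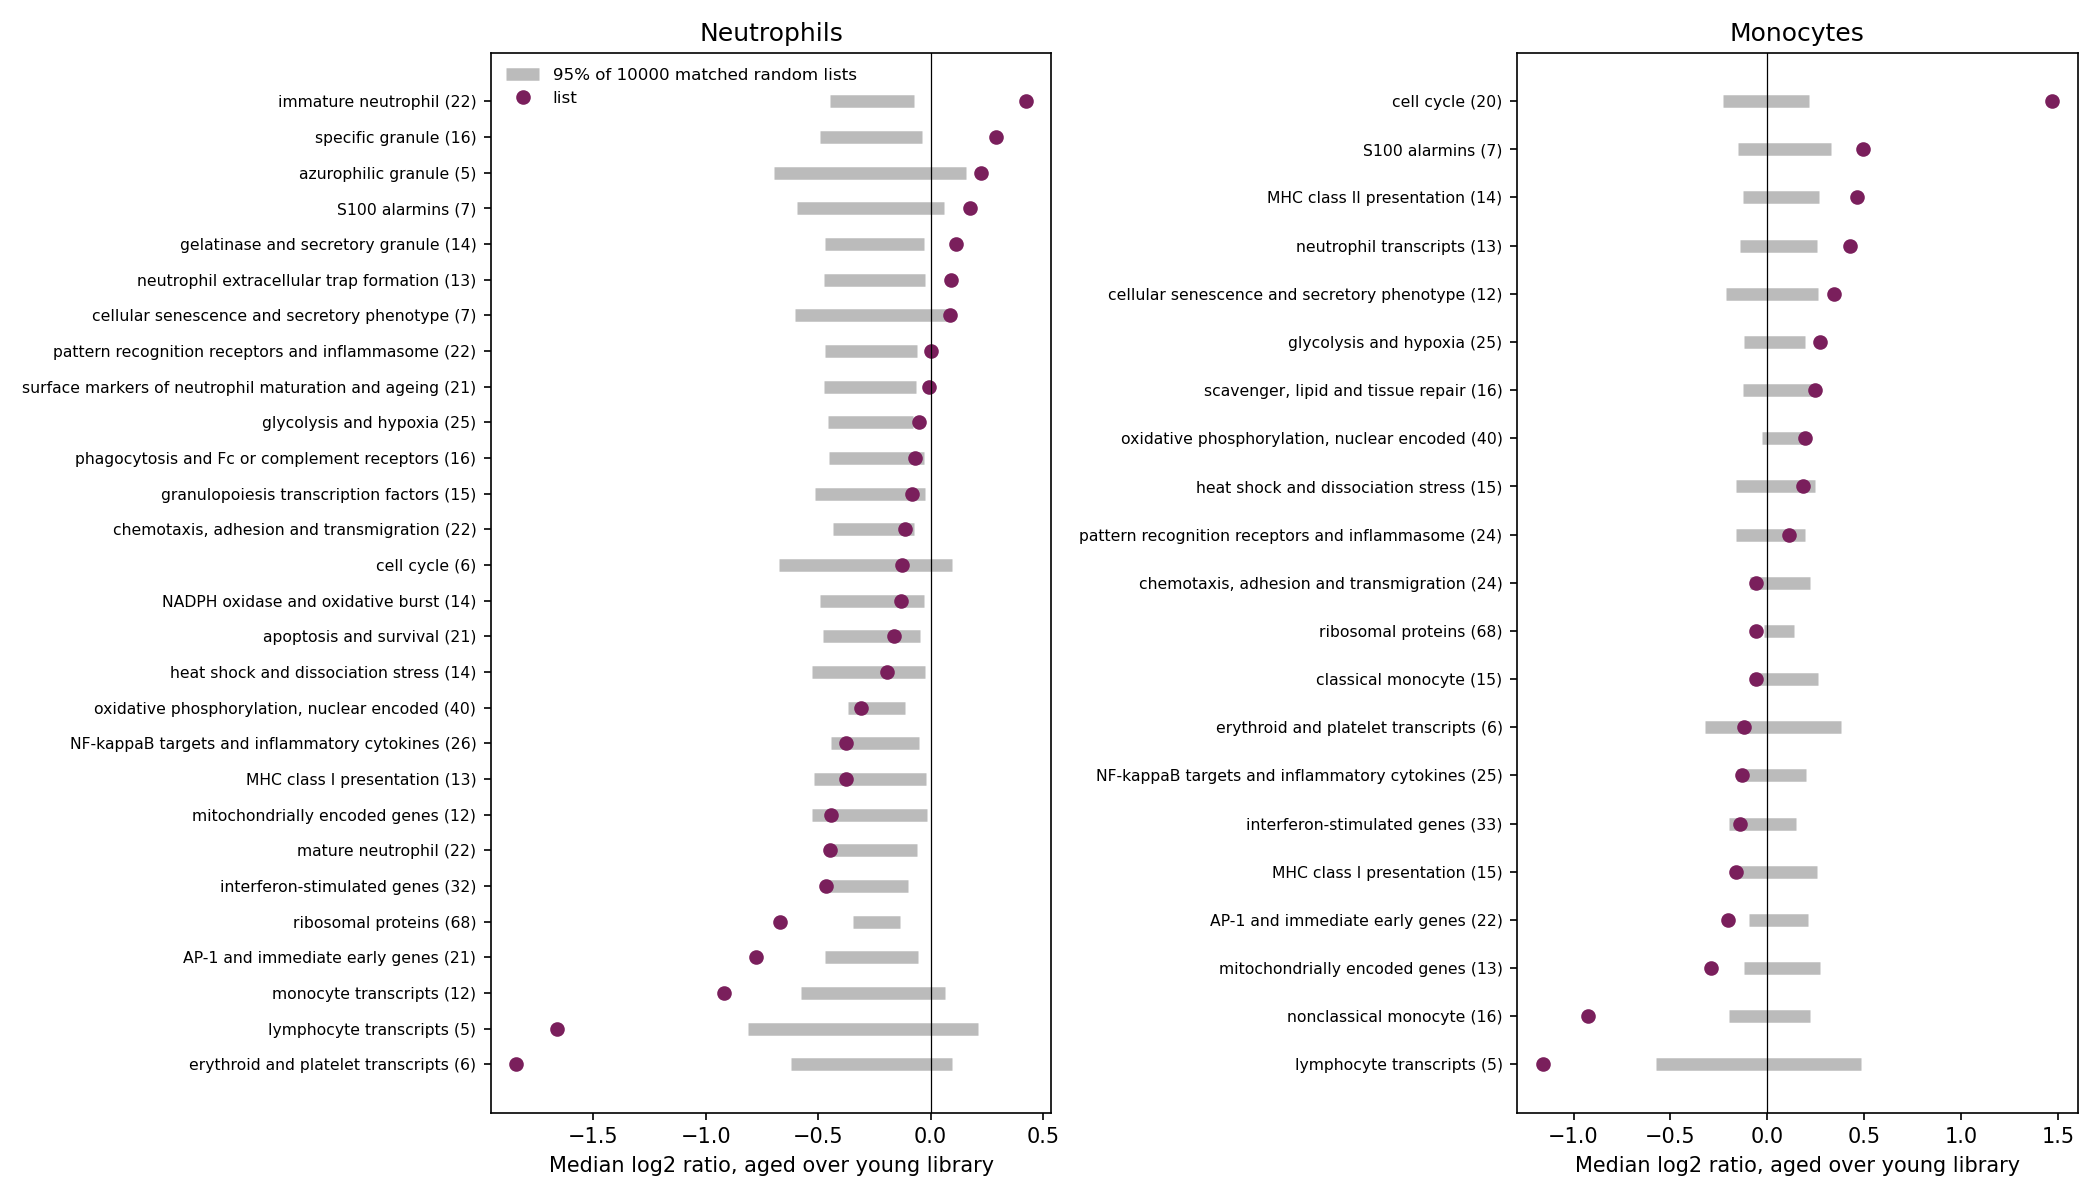
Median log2 ratio of aged over young CPM (horizontal axes) of each gene list in neutrophils (left) and monocytes (right), with the number of measured genes in brackets. Purple points are lists and grey bars hold 95% of 10000 matched random lists; the immature neutrophil list lies at 0.42 and the cell cycle list in monocytes at 1.47.

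The third question was the same comparison in monocytes. Genes of mitosis were higher in the aged library: Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, had 5 young and 109 aged UMIs, a ratio of 12.2 (5.07 to 38.3). Birc5, which encodes the chromosomal passenger protein survivin, had a ratio of 7.68 (4.93 to 12.6). Spp1, which encodes the secreted glycoprotein osteopontin, was at 36.2 and 161 CPM, a ratio of 4.44 (3.70 to 5.37). Of 16 nonclassical monocyte genes 13 were lower, and Cx3cr1, the fractalkine receptor gene, was at 91.7 and 30.4 CPM, a ratio of 0.332 (0.277 to 0.397). Of 14 MHC class II genes 5 were at least 1.5-fold higher, and this list did not stand above matched lists with own clusters at resolution 1. Values came from 538 young and 943 aged monocytes with 3621592 and 6470926 UMIs.

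Other mitotic genes ranked high in aged monocytes. Ccnb2 and Ccna2, the cyclin B2 and cyclin A2 genes, had ratios of 5.06 (3.84 to 6.77) and 10.3 (3.33 to 51.3), the latter from 3 young UMIs. Cdc20, an activator of the anaphase-promoting complex, had a ratio of 7.92 (3.70 to 20.2), Cdca3 of 6.44 (3.73 to 12) and the spindle gene Tacc3 of 7.72 (3.15 to 24.5). Stmn1, a microtubule-destabilising protein gene, had a ratio of 4.16 (3.28 to 5.34). Dmkn, which encodes the secreted protein dermokine, was at 41.7 and 228 CPM, a ratio of 5.47 (4.62 to 6.51). Among genes that ranked lowest, Cd300e, a receptor of nonclassical monocytes, had a ratio of 0.285 (0.174 to 0.457), and Lpl, lipoprotein lipase, of 0.240 (0.137 to 0.408). Ratios were 0.191 (0.0936 to 0.367) for Sdc3, a syndecan gene, 0.213 (0.118 to 0.367) for Mpv17l, and 0.322 (0.25 to 0.412) for Adrbk2, a G protein-coupled receptor kinase gene. The AP-1 gene Fosb had a ratio of 0.352 (0.265 to 0.466). Gzma, at 0.174 (0.108 to 0.270), and the chemokine gene Ccl5, at 0.334 (0.275 to 0.404), are abundant in NK cells, whose share was lower in the aged library. Wdr89 had a ratio of 0.296 (0.283 to 0.310). On GRCm38/mm10, Birc5 lies on chromosome 11 from 117849251 to 117855743, Spp1 on chromosome 5 from 104435118 to 104441050, Dmkn on chromosome 7 from 30763756 to 30781063, and Cx3cr1 on chromosome 9 from 119901616 to 120069879.

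Of 7787 monocyte genes with at least 50 UMIs, 110 were at least 2-fold higher in the aged library and 169 at least 2-fold lower, with a median log2 ratio of 0.01. Simulated libraries with no difference, again with counting error alone, gave 10 and 0 of 7791 genes. The split was 51 and 93 with own clusters at resolution 2, 767 and 885 in thinned cells, 201 and 328 with genes from 20 UMIs, and 36 and 50 with genes from 200 UMIs. With own clusters at resolution 2 the log2 ratio of Ube2c went from 3.61 to 1.26, of Dmkn from 2.45 to 1.24 (the cluster led by Spp1 and Dmkn then lay outside the monocytes), of Cx3cr1 from −1.59 to −0.69 and of Cd300e from −1.81 to −0.52, and at resolution 1 that of Spp1 went from 2.15 to 3.03. Classical monocytes kept at resolution 2 came largely from different clusters in the young and aged libraries, the mainly young cluster led in part by ribosomal pseudogene copies. Monocyte values at that resolution therefore compare cells of unlike clusters.

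Of 20 measured cell cycle genes in monocytes, 13 were higher and none lower, with a median log2 ratio of 1.47 at percentile 100. H2afz, a histone variant gene, was at 1.29 (1.25 to 1.33) and Hmgb2, a chromatin protein gene, at 1.61 (1.53 to 1.69), while Pcna, the replication clamp gene, was at 0.831 (0.666 to 1.04). The excess over matched lists was 1.47, and it was 0.22 and 0.06 in monocytes defined by own clusters at resolutions 0.5 and 2, 0.23 at resolution 1 and 0.00 with each library clustered alone. In the joint clusterings the cycling cells formed a cluster outside the monocytes, with a granulocyte or stem progenitor name from the marker lists. At resolution 1 it held 13 of the 538 young and 134 of the 943 aged monocytes. The cell cycle ratios may therefore come from a larger part of such cells and do not show a change within the other monocytes. The aged library clustered alone also gave such a cluster, of 130 cells, and the young library alone gave none, so that with each library alone unlike cells were compared. Log2 ratios of Birc5, Ccna2, Cdc20 and Hmgb2 became −0.33, −0.69, −1.5 and −0.03 with each library clustered alone, and that of H2afz −0.10 at resolution 2.

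Birc5 UMIs were found in 2.42% (1.29% to 4.10%) of young and 13% (11% to 15.4%) of aged monocytes without thinning and in 1 and 17 cells at 500 UMIs. Neither 83 young nor 99 aged NK and B cells held one. Spp1 UMIs were found in 7.25% (5.21% to 9.78%) and 28.3% (25.5% to 31.3%) unthinned and in 1.30% and 5.30% thinned, against 0 and 3.03% unthinned and 0 and 0 thinned in NK and B cells. Ccnb2 UMIs were found in 4.65% and 20.6% unthinned and 0.743% and 3.61% thinned, against 0 and 1.01%, and 0 and 0. Median depth was 6638 and 6393 UMIs in monocytes, against 2079 and 2654 in NK and B cells.

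Genes of monocyte subsets were compared next. Of 16 nonclassical monocyte genes 13 were lower and 1 higher, with a median log2 ratio of −0.93 at percentile 0. Own clustering at resolution 1 put 94 of the 538 young and 82 of the 943 aged monocytes in a nonclassical cluster, so these ratios may come from a smaller part of such cells and do not show a change within them. Nr4a1, the transcription factor these cells depend on, was at 0.524 (0.457 to 0.601) and Pou2f2 at 0.526 (0.468 to 0.591), while the tetraspanin gene Cd9 was at 2.03 (1.62 to 2.56). The fatty acid transport genes Cd36 and Fabp4 were at 0.338 (0.211 to 0.534) and 0.346 (0.204 to 0.578), and their log2 ratios of −1.57 and −1.53 both became 0.57 with own clusters at resolution 0.5. That resolution gave no nonclassical cluster and left a single cluster, named classical, to compare. It held 431 young and 679 aged labelled monocytes, against 394 and 565 in the classical cluster at resolution 1, so other monocytes were among them. The distance of the list from matched lists went from −0.94 to −0.45 at resolution 0.5 and to −0.16 at resolution 2. Classical monocyte genes had a median of −0.06 at percentile 4.58, with none of 15 beyond 1.5-fold. Ccr2, the receptor for exit from marrow, was at 0.944 (0.906 to 0.984), Fn1 at 0.687 (0.654 to 0.722), Lyz2 at 0.712 (0.704 to 0.720) and Hp, which encodes haptoglobin, at 1.34 (1.30 to 1.39). The small Ccr2 difference turned to a log2 ratio of 0.07 in cells thinned to 500 UMIs, and the distance of the list from matched lists went from −0.13 to 0.02. Ly6c2 was at 1.16 (1.11 to 1.21), a log2 ratio of 0.21 that became −0.59 at resolution 2.

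MHC class II genes had a median log2 ratio of 0.47 at percentile 99.99, with 5 of 14 higher and none lower. H2-Eb1 was at 1.83 (1.66 to 2.03), H2-Ab1 at 1.76 (1.64 to 1.89) and Cd74, the invariant chain, at 1.67 (1.60 to 1.75). The excess of this list over matched lists, 0.41, became 0.08 with own clusters at resolution 0.5, −0.01 at resolution 1 and 0.74 with each library alone. Log2 ratios of H2-Ab1 and H2-Aa became −0.17 and −0.12 at resolution 0.5, and that of Cd74 went from 0.74 to 0.01 at resolution 1 and 2.90 with each library alone. At resolution 1 a cluster led by C1q genes, with 34 of the 538 young and 156 of the 943 aged monocytes, left the monocytes of both libraries under a dendritic name, so the higher MHC class II values may come from a larger part of such cells. Of the settings given here for MHC class II, that with each library alone compares unlike cells, since the C1q cells fell under a dendritic name in the young and under nonclassical monocytes in the aged library. MHC class I genes had a median of −0.16 at percentile 2.51, with none of 15 beyond 1.5-fold and the peptide transporter gene Tap1 at 0.760 (0.625 to 0.925). Scavenger, lipid and tissue repair genes had a median of 0.25 at percentile 97.0, with 5 of 16 higher and 2 lower, Plin2, a lipid droplet coat protein gene, at 1.56 (1.45 to 1.67) and Thbs1 at 1.96 (1.70 to 2.26).

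Of 13 neutrophil transcripts in monocytes 5 were higher and none lower, with a median of 0.43 at percentile 99.99. S100a8 and S100a9 were at 1.44 (1.43 to 1.46) and 1.64 (1.61 to 1.66), Retnlg at 1.33 (1.29 to 1.37), Ly6g at 2.20 (1.62 to 3.03) and Il1r2 at 3.22 (2.90 to 3.59), while Csf3r was at 0.780 (0.680 to 0.896). Of that list's 15 genes 5 also stand in another monocyte list. S100a8 reached 107.7 UMIs per young and 158.5 per aged monocyte, 10.8 and 31.8 per NK cell, and 31.2 and 82.3 per B cell. The S100 list, which shares S100a8 and S100a9, had a median of 0.49 at percentile 99.9, with 2 of 7 higher, including S100a10 at 1.76 (1.69 to 1.84). The excess of the S100 list over matched lists, 0.44, became 0.07 with own clusters at resolution 2, and that of the neutrophil list went from 0.38 to 0.16.

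Among inflammatory groups in monocytes, AP-1 and immediate early genes had a median log2 ratio of −0.20 at percentile 0.05, with 6 of 22 lower and none higher, and Egr1 at 0.468 (0.351 to 0.623). The distance from matched lists went from −0.26 to −0.09 at resolution 2. Interferon-stimulated genes had a median of −0.14 at percentile 10.3, with 2 of 33 lower, the antiviral gene Oas3 at 0.595 (0.392 to 0.906) among them. NF-kappaB targets had a median of −0.13 at percentile 4.08, with 4 of 25 higher and 4 lower. Nfkbiz, an atypical inhibitor of kappaB gene, was at 0.560 (0.454 to 0.690), a log2 ratio of −0.84 that became 0.51 in thinned cells, and Sod2 was at 1.55 (1.36 to 1.77). The distance of the NF-kappaB list from matched lists, −0.15, became 0.25 both at resolution 2 and in thinned cells, and that of the interferon list, −0.11, became 0.26 in thinned cells. Pattern recognition genes had a median of 0.11 at percentile 85.1, with none of 24 beyond 1.5-fold and Pycard, the inflammasome adaptor, at 1.41 (1.34 to 1.48). Chemotaxis genes had a median of −0.06 at percentile 6.65, with 5 of 24 higher and 4 lower, Ltb4r1 at 2.08 (1.88 to 2.32) and C5ar1 at 1.96 (1.77 to 2.18). Their distance from matched lists, −0.12, became 0.05 at resolution 2. Senescence and secretory genes had a median of 0.34 at percentile 99.7, with 4 of 12 higher, Lmnb1 at 1.77 (1.44 to 2.19) and the metalloproteinase inhibitor Timp1 at 2.46 (1.39 to 4.65), while Cdkn1a, the cell cycle inhibitor p21, was at 0.741 (0.658 to 0.834). The list sets no direction for its genes, and with Lmnb1 higher and Cdkn1a lower its median is not read as senescence. The log2 ratio of Timp1 went from 1.30 to 0.09 at resolution 2.

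Glycolysis and hypoxia genes had a median of 0.27 at percentile 99.8, with 6 of 25 higher and 1 lower, Pgk1, a glycolytic kinase gene, at 2.14 (1.77 to 2.59) and Hk2 at 0.527 (0.433 to 0.640). Nuclear oxidative phosphorylation genes had a median of 0.19 at percentile 98.0, with none of 40 beyond 1.5-fold and the ATP synthase gene Atp5b at 1.46 (1.38 to 1.55). With own clusters at resolution 2 the excess over matched lists went from 0.24 to 0.04 for glycolysis and from 0.12 to −0.01 for oxidative phosphorylation. Mitochondrially encoded genes had a median of −0.29 at percentile 0.135, with 2 of 13 lower, and mt-Atp8 at 0.360 (0.275 to 0.470). Ribosomal protein genes had a median of −0.06 at percentile 0.01, with 5 of 68 lower, Rps28 at 0.431 (0.421 to 0.440) among them, and their distance from matched lists went from −0.12 to −0.07 among genes from 200 UMIs. Heat shock genes had a median of 0.18 at percentile 90.0, with 1 of 15 lower and the chaperone gene Hspa5 at 1.38 (1.28 to 1.49), whose log2 ratio of 0.47 became −0.04 at resolution 2. The heat shock excess went from 0.14 to 0.40 in thinned cells. Lymphocyte transcripts had a median of −1.16 at percentile 0.02, with 3 of 5 lower and Nkg7 at 0.448 (0.262 to 0.758), and their distance from matched lists went from −1.12 to −2.13 in thinned cells. Erythroid and platelet transcripts had a median of −0.12 at percentile 16.5, with 2 of 6 higher and 2 lower, Pf4 at 1.98 (1.14 to 3.61) and Hbb-bs at 0.548 (0.511 to 0.589), a log2 ratio of −0.87 that became 0.37 at resolution 2. Their distance from matched lists, −0.17, ranged from −2.17 with each library alone to 0.77 at resolution 2.

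Other monocyte genes named here had a ratio that differed by more than 1.5 times from the value above under a further setting, given here as log2. Resolution 0.5 of own clusters gave 2.29 for Birc5, 1.74 for Ccnb2, −0.65 for Cd300e, 2.15 for Cdc20, 1.76 for Cdca3, −1.46 for Lpl, −1.65 for Sdc3, 1.74 for Tacc3, 0.41 for Timp1 and 2.67 for Ube2c. Resolution 2 of own clusters gave −0.70 for Adrbk2, 0.68 for Cdc20, 1.49 for Cdca3, −0.44 for Egr1, −0.19 for Fabp4, −2.78 for Lpl, −1.49 for Mpv17l, −1.95 for Nkg7, −0.16 for Nr4a1, 0.22 for Pf4, 1.36 for Stmn1 and 2.09 for Tacc3. With each library clustered alone it became 0.21 for Ccnb2, 0.93 for Cdca3, 2.74 for H2-Aa, 2.52 for H2-Ab1, 3.32 for H2-Eb1, −2.06 for Hbb-bs, 0.84 for Stmn1, 1.57 for Tacc3, 0.20 for Timp1 and 1.51 for Ube2c. Resolution 1 of own clusters gave 1.44 for Cdc20, −0.29 for H2-Aa, 0.094 for H2-Ab1, 0.18 for H2-Eb1, 2.09 for Tacc3, 0.32 for Timp1 and 2.88 for Ube2c. With the mean of each cell's CPM it became 2.70 for Ccna2, 1.80 for Cdca3 and −0.88 for Fabp4. In cells thinned to 500 UMIs it became −0.43 for Egr1, −2.39 for Fabp4, −3.81 for Gzma, 0.14 for H2-Eb1, −2.39 for Hk2, 0.45 for Ly6g, −0.81 for Mpv17l, −2.39 for Oas3, 0.19 for Pf4, 0.46 for Pgk1 and 1.38 for Stmn1.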

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

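Results were brought out here either because they appeared in cells that no comparison of the report used, or because neutrophils and monocytes went opposite ways. Cells labelled Mast cell were 42 of the aged library, 1.10% of its cells, above 0.165%, the one-sided 95% limit for 0 of 1822 young cells. Genes for this group were chosen after its leading genes were seen. Mcpt8, a basophil protease gene, was at 3565 CPM and in 73.8% of the 42 cells, Cd200r3 in 95.2%, Fcer1a, the IgE receptor alpha chain gene, in 85.7%, and Gata2, a transcription factor of basophils and mast cells, in 71.4%. The protease gene Cpa3, which the marker lists hold for basophils and mast cells together, had 14 UMIs in 8 of the 42 cells, 19.0%. Of mast cell genes, Cma1 had 0 UMIs and Kit had 1.

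Genes went opposite ways in the populations with both intervals clear of 1, and the difference between neutrophils and monocytes was not tested. Log2 ratios of aged over young in neutrophils and in monocytes were −0.40 and 0.74 for Cd74, −0.89 and 0.77 for H2-Aa, −0.95 and 0.29 for Il1b, −0.78 and 0.63 for Sod2, −0.62 and 0.32 for Slpi, −0.81 and 0.69 for Hmgn2, −0.92 and 0.53 for Ms4a4c and −0.79 and 0.15 for Psmb8. They were −0.42 and 0.47 for Hspa5, −0.31 and 0.11 for Cox8a, −0.12 and 0.59 for Cxcr2, −0.12 and 0.17 for Fcer1g, −0.23 and 0.33 for Slfn1, −0.60 and 0.07 for Rps6, −0.37 and 0.03 for Rps9, and 0.42 and −0.15 for Mmp8. Most of these oppositions did not hold in every setting. In neutrophils Cxcr2 and Fcer1g became 0.19, Slfn1 0.079 and Cox8a about 0 with TMM scaling, and Ms4a4c became 0.060 and Sod2 −0.011 in thinned cells. In monocytes H2-Aa became −0.12 and Cd74 0.012 with own clusters at resolutions 0.5 and 1, and Hspa5, Rps6 and Hmgn2 −0.037, −0.028 and −0.41 at resolution 2. Monocyte Slfn1 became −0.11 in thinned cells, and Rps9 −0.039 with ribosomal and mitochondrial genes left out of the total and −0.0022 in thinned cells. Il1b, Slpi, Psmb8 and Mmp8 kept theirs. Cd74, H2-Aa and Ms4a4c stand in lists made for monocytes, and monocyte transcripts in neutrophils had a median of −0.92. Cxcr2 stands in the neutrophil transcript list, whose median in monocytes was 0.43, while Mmp8 of that list was lower there. Free RNA of other cells as a source of such values was not tested for these genes.

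Of the tests below, those of S100a8, Il1r2, the ribosomal copies, the ribosomal protein genes in other cells, the progenitor markers and the lowest depth were chosen after the result was seen, and those of free monocyte RNA, early cells and doublets were written before the values they measure, with the patterns themselves already seen.

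The immature neutrophil list, 7 of 22 genes higher and 2 lower (14 and 0 with TMM scaling), was set against 2 technical explanations. With the same lowest depth in both libraries the list still lay 0.57 log2 above matched lists, where the explanation needed less than 0.2. Without the cells that held a UMI of Camp, Ltf or Ngp, 32.9% of young and 49.0% of aged neutrophils, it lay 0.56 above them, with 4 of 19 measured genes higher and 3 lower by 1.5-fold, so that in the median neither the depth floor nor those cells alone carried it. A larger part of younger neutrophils in the blood of the aged library could give this pattern, but the sort, the spread between mice and the library batch stay untested, and age cannot be told apart from them.

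Ribosomal protein genes were 6.12% of young and 3.80% of aged neutrophil UMIs, and 26.1% and 23.4% in monocytes. Free monocyte RNA, at most 2.82% of young neutrophil UMIs by monocyte genes, would bring 0.316 of the neutrophil gap and did not account for it. Ribosomal pseudogene copies lay below the ribosomal protein genes by at least 1.12 log2 in each of 4 populations (smallest gap −1.12), which fits reads being given differently to near-identical copies in the 2 libraries. The gap in monocytes, 1.39, excluded lower ribosomal transcription as the cause for the copies. The ribosomal protein genes themselves had a median log2 ratio of −0.67 (quartiles −0.82 and −0.57) in neutrophils, and −0.06 in monocytes, −0.06 in conventional dendritic cells and 0.13 in NK cells of the same libraries. With total scaling, lower quartiles in those cells lay at least 0.40 above the upper quartile in neutrophils. Under that scaling this excludes an effect of the sequencing run or library alike in all cells as the whole cause. TMM scaling adds 0.31 to neutrophil and 0.0076 to monocyte log2 ratios and so narrows the gap. Its factors were not computed for dendritic and NK cells, so the exclusion was not checked under it. An effect on neutrophils alone, from handling or from age, was not tested and stays open.

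Cycling monocytes were set against doublets, with limits of 3 UMIs and 1.5-fold, and 5 broadly expressed genes left out, all set by hand after list values had been seen. Of monocytes with at least 3 cell cycle UMIs out of 1000 there were 3 of 538 young and 30 of 943 aged. Beside other aged monocytes these held 1.42 times the S100a8 UMIs per cell, close to the 1.5 limit, and 0.417, 0.298 and 0.387 times the NK, B cell and erythroid markers. NK and B cell markers were at only 17.4 and 4.34 CPM in the cycling cells, so those 2 ratios rest on low counts. The S100a8 value was not adjusted for depth, whose median was 7337 UMIs in the cycling and 6357 in the other aged monocytes. By these markers, doublets with lymphoid or erythroid cells did not account for these 30 cells, while for doublets with neutrophils the margin was narrow. Cells with the highest doublet scores had been removed beforehand. Release of dividing progenitors into the blood could give this pattern, but progenitor markers were at 382 CPM in the cycling and 329 CPM in the other aged monocytes, a ratio of 1.16 (0.927 to 1.44), which by itself neither supports nor excludes it. In the young library these markers were at 197 CPM in the 3 cycling and 215 CPM in the other monocytes, with no interval made. Elane, 1 of these markers, was a leading gene of the Spp1 and Dmkn cluster with 331 aged cells, so the other aged monocytes were not free of them. Own clusters at resolution 1 gave a cycling cluster, with 13 young and 134 aged monocytes, a granulocyte or stem progenitor name. It held more aged cells than the 30 counted here, so the other aged monocytes also held cycling cells, and the ratio does not set cycling against non-cycling cells alone. With each library clustered alone the Birc5 log2 ratio was −0.33. That setting took a cycling cluster out of the aged monocytes only, so it does not compare like with like.

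The S100a8 gain in monocytes, 50.8 UMIs per cell, was 0.994 times the largest gain in NK, B and dendritic cells. That largest gain, 51.1, was in B cells, of which there were only 14 young and 41 aged. It was smaller in dendritic cells, at 39.4, and in NK cells, which went from 10.8 to 31.8 UMIs per cell. Gains were not adjusted for depth. Free neutrophil RNA therefore fits by B cells alone, and the test does not decide whether it accounts for the S100a8 gain in monocytes. The lower bound of Il1r2 in aged monocytes was 2.63 times the level that all of their S100a8 would bring from neutrophils, which excludes free neutrophil RNA as its whole source.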

How the results depend on the processing

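No paired analysis was possible because each group held 1 library, and no library could be left out for the same reason. Leaving out the filter on cells changed nothing, since the filter removed 0 cells. Of the values compared over all alternatives, 2300 log2 ratios of single genes stayed within their interval, 353 moved and 34 reversed. Of those that stayed, 579, 193 each under no filter and under both other minimums of UMIs per gene, could not change, which leaves 1721. Of list values 608 stayed, 73 moved and 2 reversed, of shares of cells 16 stayed and 16 moved, of gene numbers 38 stayed and 18 moved, and all 8 shares of UMIs per cell stayed. Among the list values that stayed, 49 each under no filter, under TMM scaling and with ribosomal and mitochondrial genes left out of the total could hardly move, since a factor common to all genes shifts a list and its matched lists alike. The immature neutrophil list lay 0.55 to 0.69 above matched lists in every setting. In neutrophils the mature list lay at −0.26 to −0.17, the AP-1 list at −0.55 to −0.27 and the ribosomal list at −0.44 to −0.41 in every setting. Reversed values, and list values, shares and gene numbers that moved, follow by setting. List values are the median log2 ratio minus that of matched lists. Own clusters placed part of the cells that the authors labelled monocytes under other names. In the joint clusterings the same clusters left both libraries, at resolution 1 with 34 young and 156 aged (C1q) and 13 and 134 (cycling) monocytes, so the labelled monocytes hold unequal parts of them. At resolution 2 a cluster led by Spp1 and Dmkn, with 34 young and 331 aged labelled monocytes, left as well. Classical monocytes kept there lay in a cluster of 297 young and 32 aged cells, led in part by ribosomal pseudogene copies, and another of 50 and 197. Resolution 2 therefore also compares cells of unlike clusters. Whether those 2 clusters are unlike kinds of monocyte was not tested. With each library alone unlike cells are compared. The aged library clustered alone also lost cells with Ppbp and Pf4 from its neutrophils, which the young did not. Otherwise the cause was not tested. Depth limits genes near 50 UMIs, whose intervals are wide, and thinned sums, which hold fewer counts.

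With at least 500 genes and 1000 UMIs per cell, the neutrophil share was 57.1% (young) and 60.1% (aged). The neutrophil list values were 0.60 (specific granule) and 0.39 (S100). The monocyte share was 34.2% (young) and 31.5% (aged). Without doublet removal, the monocyte list values were 0.56 (neutrophil transcript). With own clusters at resolution 0.5, the monocyte share was 23.9% (young) and 17.8% (aged). The monocyte list values were 0.22 (cell cycle), −0.11 (ribosomal), −0.019 (chemotaxis), 0.20 (erythroid and platelet), −0.45 (nonclassical monocyte), 0.083 (MHC class II) and 0.28 (scavenger). Reversed monocyte log2 ratios were 0.57 (Cd36), 0.57 (Fabp4), −0.12 (H2-Aa) and −0.17 (H2-Ab1).

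With own clusters at resolution 2, the neutrophil share was 66.6% (aged). The monocyte share was 24.9% (young) and 8.19% (aged). Monocyte genes at least 2-fold apart numbered 51 higher and 93 lower. The monocyte list values were 0.25 (NF-kappaB), −0.093 (AP-1), 0.065 (S100), 0.058 (cell cycle), 0.042 (glycolysis), −0.014 (oxidative phosphorylation), 0.049 (chemotaxis), 0.77 (erythroid and platelet), 0.16 (neutrophil transcript) and −0.16 (nonclassical monocyte). Reversed monocyte log2 ratios were 0.036 (Cd36), −0.10 (H2afz), 0.37 (Hbb-bs), −0.41 (Hmgn2), −0.037 (Hspa5), −0.20 (Lcn2), −0.59 (Ly6c2) and −0.028 (Rps6).

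With each library clustered alone, the neutrophil share was 66.5% (aged). The neutrophil list values were −2.54 (erythroid and platelet). Reversed neutrophil log2 ratios were −0.48 (Pf4) and −1.38 (Ppbp). The monocyte share was 27.3% (young) and 21.1% (aged). Monocyte genes at least 2-fold apart numbered 71 higher. The monocyte list values were −0.18 (AP-1), 0.38 (S100), 0.0010 (cell cycle), 0.039 (oxidative phosphorylation), −0.10 (ribosomal), −2.17 (erythroid and platelet), −0.73 (nonclassical monocyte), 0.74 (MHC class II) and 0.28 (scavenger). Reversed monocyte log2 ratios were −0.33 (Birc5), −0.69 (Ccna2), −1.50 (Cdc20) and −0.028 (Hmgb2).

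With own clusters at resolution 1, an alternative added after seeing the data, the monocyte share was 26.9% (young) and 17.0% (aged). Monocyte genes at least 2-fold apart numbered 62 higher. The monocyte list values were 0.55 (S100), 0.23 (cell cycle), 0.29 (erythroid and platelet), −0.058 (classical monocyte) and −0.012 (MHC class II). Reversed monocyte log2 ratios were −0.29 (H2-Aa). With the same lowest depth of 1451 UMIs in both libraries, also added after seeing the data, the neutrophil share was 54.4% (young). The neutrophil list values were 0.47 (specific granule), 0.57 (immature neutrophil), 0.38 (S100), 0.10 (glycolysis) and 0.31 (granulopoiesis factor). The monocyte share was 35.9% (young).

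With ribosomal and mitochondrial genes left out of the total, reversed monocyte log2 ratios were −0.039 (Rps9). With TMM scaling, neutrophil genes at least 2-fold apart numbered 131 higher and 95 lower. Reversed neutrophil log2 ratios were 0.23 (Cebpb), 0.19 (Cxcr2), 0.19 (Fcer1g), 0.045 (Mcl1), 0.079 (Slfn1), 0.10 (Wfdc21) and 0.086 (mt-Co1). The median log2 ratio of all neutrophil genes was −0.24, and 0.07 with TMM scaling. The split of 47 higher and 253 lower genes became 131 and 95, and 105 and 116 with centred ratios, so the direction of single neutrophil genes near 1 rests on the scaling. Neutrophil sub-clusters numbered 4 at resolution 0.5, 2 at resolution 0.3 and 9 at resolution 1.

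In cells thinned to 500 UMIs, neutrophil genes at least 2-fold apart numbered 171 higher and 536 lower. The neutrophil list values were 0.46 (specific granule), 0.23 (gelatinase granule), 0.55 (immature neutrophil), −0.24 (mature neutrophil), 0.34 (maturation surface), 0.57 (extracellular trap), −0.41 (ribosomal) and 0.36 (senescence). Reversed neutrophil log2 ratios were 0.060 (Ms4a4c). Monocyte genes at least 2-fold apart numbered 767 higher and 885 lower. The monocyte list values were 0.26 (interferon), 0.25 (NF-kappaB), 0.50 (S100), −0.42 (mitochondrial), −0.11 (ribosomal), 0.40 (heat shock), −0.023 (chemotaxis), −1.09 (erythroid and platelet), −2.13 (lymphocyte), 0.27 (neutrophil transcript) and 0.024 (classical monocyte). Reversed monocyte log2 ratios were 0.074 (Ccr2), 0.16 (Itgal), 0.51 (Nfkbiz), −0.0022 (Rps9), −0.11 (Slfn1) and 0.019 (mt-Co3).

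With minimums of 10 UMIs for list genes and 20 for single genes, neutrophil genes at least 2-fold apart numbered 126 higher and 561 lower. The neutrophil list values were 0.15 (senescence). Monocyte genes at least 2-fold apart numbered 201 higher and 328 lower. With at least 200 UMIs per gene, neutrophil genes at least 2-fold apart numbered 14 higher and 66 lower. The neutrophil list values were 0.45 (specific granule), −0.26 (mature neutrophil), −0.27 (AP-1), 0.090 (NADPH oxidase) and 0.36 (S100). Monocyte genes at least 2-fold apart numbered 36 higher and 50 lower. The monocyte list values were 0.47 (S100), 0.62 (cell cycle), −0.069 (ribosomal), −0.60 (erythroid and platelet) and −0.77 (nonclassical monocyte). With the mean of each cell's CPM, the monocyte list values were −0.22 (AP-1), 0.51 (S100), −0.13 (ribosomal), −0.68 (erythroid and platelet) and −0.056 (classical monocyte).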

Other observations

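In conventional dendritic cells, 52 young and 105 aged, 11 of 16 measured interferon-stimulated genes were lower in the aged library and none higher, with a median log2 ratio of −0.85 at percentile 0. Genes here were chosen after their values were seen. Isg15, a ubiquitin-like interferon-induced gene, had a ratio of 0.156 (0.0651 to 0.335), Ifi204, a nucleic acid sensor gene, of 0.357 (0.192 to 0.650) and Irf7, the transcription factor of the interferon response, of 0.398 (0.230 to 0.680). NF-kappaB targets had a median of 0.36 at percentile 99.4, with 5 of 19 higher and 2 lower and the neutrophil-attracting chemokine gene Cxcl2 at 3.65 (2.19 to 6.49). Cd209a, a lectin of type 2 dendritic cells, was at 0.385 (0.317 to 0.467). Neutrophil transcripts had a median of 1.19 at percentile 100 in these cells, with S100a8 at 2.28 (2.17 to 2.40).

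In NK cells, 69 young and 58 aged, 3 of 11 chemotaxis genes were lower in the aged library and none higher, with a median log2 ratio of −0.40 at percentile 1.56. Own clustering at resolution 1 put 2 of the young and 10 of the aged cells under T cells. Without them, a setting chosen after seeing the data, that list had 2 lower and 1 higher and a median of −0.19 at percentile 12.8, within the range of matched lists. The chemokine gene Ccl4 was at 0.185 (0.112 to 0.293) and Klra7, an inhibitory Ly49 receptor gene, at 0.367 (0.230 to 0.570), while Gzma was at 1.04 (0.965 to 1.11). Without those cells they were at 0.193 (0.112 to 0.314), 0.442 (0.277 to 0.687) and 1.25 (1.16 to 1.34). MHC class I genes had a median of 0.34 at percentile 99.8, with 2 of 14 higher and none lower, and without those cells of 0.18 at percentile 93.8. Neutrophil transcripts had a median of 1.39 at percentile 100 and S100 genes of 1.23 at percentile 100, with S100a8, a gene of neutrophils and monocytes, at 2.62 (2.41 to 2.86), and both stayed at percentile 100 without those cells.

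Genes of the Y chromosome were present in both libraries. Ddx3y was at 39.8 and 32.3 CPM in the young and aged library, Eif2s3y at 62.1 and 53.2, Kdm5d at 4.42 and 3.79 and Uty at 6.63 and 6.44. In cells thinned to 1000 UMIs, neutrophils with at least 2 UMIs summed over 3 platelet genes were counted. They were 0.176% (0.0213% to 0.635%) of the young and 0.459% (0.237% to 0.800%) of the aged neutrophils. Thinning lowers such shares. Without it, the cluster led by Pf4 and Ppbp at resolution 1 held 4 young and 55 aged cells labelled neutrophils.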
